A study of Homo sapiens with 8 samples.

How the data were processed

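Total RNA of HCT116 cells was labelled with Cy3 and hybridised to Agilent human miRNA arrays, 1 colour per array. The intensity values of each array were made by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. Per the file headers, the processed signal is a spot intensity after background subtraction, with no scaling between arrays. The deposited value table of the series holds log2 values, and no source used here states how the authors made it. Set against each array's total gene signal, its values above 0 followed the same ranks, and they were 0 for every miRNA not detected. The highest ranked values were the same on all arrays, while lower ranks were not compared. This is the form of quantile normalized log2 signals. The median of the table was 0 on every array. On shTRF2 replicates 2 and 3 it held 165 values above 0, where Feature Extraction had detected 194 and 186 miRNAs, so a 0 there also covers detected miRNAs. No direction is involved, since each column is 1 sample. The table served as an alternative.

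Control spots and spots marked as outliers were left out, which took 3.79% to 5.07% of the miRNA spots of an array. Spots of a probe were averaged on the linear scale, and a probe counted as well above background when at least 50% of its spots were marked so. Each array was divided by its 75th percentile over the 90 probes well above background on all 8 arrays, values were floored at the mean over arrays of the lowest scaled signal well above background (−3.51 on the log2 scale), and log2 was taken. The floor equalled 10.7 to 33.7 signal units on single arrays, so dim miRNAs on bright arrays reached it first. A miRNA was represented by its brightest probe. Of 22 miRNAs with at least 2 probes well above background on all arrays, 18 had the same sign of difference on their probes. The 2 arrays of one RNA were averaged on the log2 scale before the fit, so n = 3 in each group. Tested were the 91 miRNAs well above background on all arrays of at least 1 group: 67 in both, 19 through shTRF2 alone and 5 through shControl alone. A miRNA that passes through 1 group alone is favoured by the filter to be higher there. The median coefficient of variation between spots ran from 35.6% to 74.0% in the file statistics. That coefficient and the labelling and hybridisation spike-in metrics lay outside the range set in the files on all 8 arrays. Both spike-in values were the same on every array, at −0.70 on the log10 scale.

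The test was limma 3.58.1 (lmFit and eBayes) in R 4.3.3, shTRF2 minus shControl, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. For single values an exact permutation test of 3 against 3 was used, which cannot go below 0.1. miR-193b-3p did not pass the filter and was added to the tested miRNAs for its own fit, 92 in all. The groups came from the labels, which also state that the samples were separate infections and that 2 arrays were technical repeats.

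The lists, 22 in number, were the miR-193 and miR-365 group, p53-induced miRNAs, miR-17-92 and paralogous clusters, the let-7 family, epithelial miRNAs, miRNAs raised in colorectal tumours, the miR-15/16, miR-29 and miR-30 families, the miR-23/27/24 clusters, the miR-221 and miR-222 cluster, miRNAs reported to target telomere or telomerase genes, inflammation and senescence miRNAs, the placental and imprinted clusters, stem cell clusters, markers of blood cells, of fibroblasts, vessels and smooth muscle, of striated muscle, of neurons and of liver, and GC-rich miRNAs as an RNA quality set. Lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. Named were every measured member of the miR-193 and miR-365 group, the 10 largest rises and the 10 largest falls past the threshold or, where fewer passed, the next by smallest p up to 10 in each direction, up to 4 bounds in each direction, and the 3 members with the largest moderated t of each list with at least 3 tested members. No bound arose. Lists, their tests, the rule for names and the alternatives, apart from 2 combined settings added later, were fixed before the data were examined. Chosen after results were seen were the test of a shared row shift and that of let-7 minus GC-rich without shControl replicate 2. Some members of smaller lists were named then too. The patterns whose explanations are weighed at the end, such as let-7 minus GC-rich, were themselves observed in these data.

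Alternatives were other scalings (75th percentile of all probes, median of detected probes, quantile normalization), normexp background correction with an offset of 50, the total gene signal, the mean of all probes, a floor of 1 unit, other filters, single arrays of the repeated samples, all 8 arrays with the RNA sample as a random block, the slide row as a term, other variance settings, the authors' table, a replicate block and each sample left out in turn. Normexp used the median spot signal and the local background median, because the files here hold no mean signal column. The 75th percentile of all probes falls among dim probes, since 4.39% to 7.48% of miRNAs were well above background on an array. Gene neighbours were read from RefSeq's table for GRCh38.p14 by name only, since the array headers name another build. The fit was tested on simulated data drawn from the means and residual SDs of the 91 miRNAs of this comparison, with 7 miRNAs changed at each size in each of 20 simulations. It recovered 51.4% of changes of 1 on the log2 scale, 92.1% of changes of 2 and 97.1% of changes of 3, and 5.07% of its calls were false. The simulated miRNAs varied independently, and many changed at once. These rates therefore do not carry over to fewer changes or to miRNAs that vary together. The fits within a slide row were tested in the same way, with the means and residual SDs of each row.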

Results

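The microRNA content of HCT116 cells, an epithelial line from a colorectal carcinoma, was measured after stable silencing of TRF2, a shelterin protein that protects chromosome ends. Cells infected with a lentiviral short hairpin against TRF2 (shTRF2) were compared with cells infected with a control hairpin (shControl), in 3 independent infections per group per the labels. RNA was taken 3 days after seeding, which followed selection by 4 days, and 100 ng was labelled with Cy3. The 6 RNA samples were hybridised to 8 arrays on 1 slide, because replicate 1 of each group was run on a repeat array. shControl replicates 2 and 3 lay only in slide row 1, and shTRF2 replicates 2 and 3 only in slide row 2. Group and slide row are therefore partly confounded in the main test. Each array carried 4774 probes for 2006 human miRNAs. Between 88 and 150 miRNAs were well above background on an array, and 67 were so on all 8 arrays. The 75th percentile of the signal of the probes detected on all arrays ran from 122.1 to 253.2 units on shControl arrays and from 164.9 to 383.2 units on shTRF2 arrays. The number of arrays limits the precision. The messenger RNA of TRF2 was not analysed here, so the knockdown itself was not checked.

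The series is named for miR-193b-3p, a miRNA encoded beside miR-365a, and the first comparison asked whether TRF2 silencing altered its level. Its signal lay close to background: 2 of 4 shControl arrays and 1 of 4 shTRF2 arrays held it well above background, while Feature Extraction called it detected on 4 of 4 and 2 of 4. Before scaling, its probe signal was 19.3 ± 2.59 units (SD, n = 3) in shControl and 17.5 ± 6.43 units (SD, n = 3) in shTRF2, and the groups overlapped (exact 2-sided permutation p = 0.8). After each array was divided by its brightness, with signals limited only below 1 unit, miR-193b-3p was lower in 3 of 3 shTRF2 samples, with means of −3.22 ± 0.33 and −4.11 ± 0.18 on the log2 scale (SD, n = 3). The difference was −0.89 (SE 0.32), with a limma adjusted p of 0.778. With the planned floor at the lowest signal well above background, all shTRF2 samples sat at the floor. The log2 difference was then −0.32 (SE 0.31, limma adjusted p = 0.789), at rank 31 of 92 by p. That difference is censored and set by the shControl samples alone, from −0.45 without shControl replicate 1 to −0.16 without shControl replicate 2. In the authors' log2 table it was listed at 0 on both arrays of shTRF2 replicate 1, where it was not detected, and at 0.65 and 0.68 on shTRF2 replicates 2 and 3, against 1.82 to 2.54 on the shControl arrays. The difference of −1.73 there had the smallest limma p of 120 miRNAs, 0.00179 before adjustment and 0.215 after it. That difference rests in part on the listed 0 and is not a measured size. Within slide row 1, 3 shControl arrays averaged −3.18 and the 1 shTRF2 array −4.03 at the floor of 1 unit. Within slide row 2 the 1 shControl array had −3.64 and 3 shTRF2 arrays averaged −4.17. With the slide row as a term and the planned floor, the log2 difference was −0.23 (limma adjusted p = 0.882). Every array of slide row 2 sat at that floor, so this value is censored too and cannot tell the row from the group. The study chose this miRNA, possibly on these samples, so its values are not independent evidence.

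**Figure D1:**
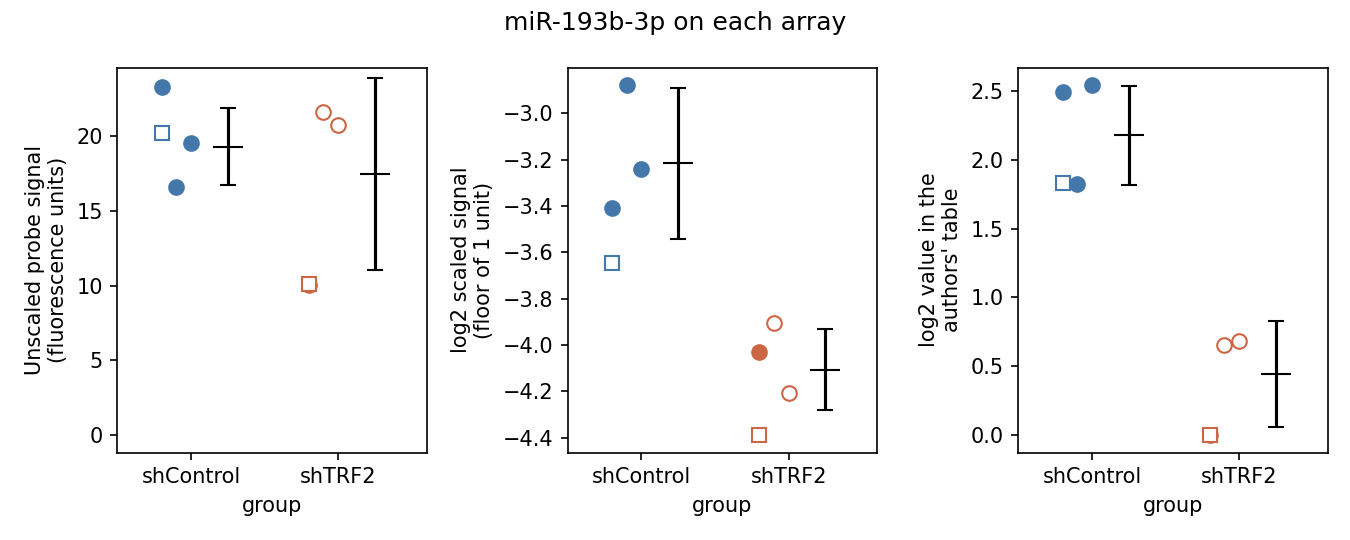
Signal of miR-193b-3p on each of the 8 arrays by group: unscaled probe signal in fluorescence units, log2 scaled signal with a floor of 1 unit, and the authors' log2 value, which is 0 for shTRF2 replicate 1, where the miRNA was not detected. Circles are first arrays, squares repeat arrays, filled symbols slide row 1, open symbols slide row 2, and black bars the mean ± SD of 3 RNA samples; unscaled signals overlapped, while both scaled versions put every shTRF2 array under every shControl array.

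The other members of the miR-193 and miR-365 group gave no comparison. miR-193a-3p, miR-193a-5p, miR-193b-5p, miR-365a-3p, miR-365a-5p and miR-365b-5p were not well above background on any array. Feature Extraction detected miR-365a-3p on 1 of 4 shControl and 1 of 4 shTRF2 arrays, with unscaled signals from 7.02 to 18.9 units. In RefSeq's gene table for GRCh38.p14, MIR193B is listed after MIR193BHG and before MIR365A. This is an order of names, which does not show whether these genes overlap.

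Across all measured miRNAs, the comparison asked which changed with TRF2 silencing, and none of the 91 tested passed. The smallest p belonged to miR-34a-5p, a p53-induced miRNA, which was lower in all 3 shTRF2 samples, at 0.559 of its shControl level (log2 −0.84, SE 0.31, limma adjusted p = 0.795). Next among lower values stood miR-22-3p, a senescence-linked miRNA (log2 −0.69, SE 0.35), and miR-320c (log2 −0.72, SE 0.36). Among higher values, let-7i-5p led (log2 0.65, SE 0.34) and was above all shControl samples in 3 of 3 shTRF2 samples, followed by miR-29b-3p (log2 0.61, SE 0.38). With the slide row as a term the log2 differences of miR-34a-5p, miR-22-3p, miR-320c, let-7i-5p and miR-29b-3p were −0.46, −0.77, −0.16, 1.02 and 0.23, and under all-probe scaling they were −0.21, −0.04, −0.09, 1.28 and 1.24. Without shControl replicate 2 miR-29b-3p was at 0.30 and miR-320c at −0.45, without shControl replicate 1 miR-29b-3p was at 0.94, and without shTRF2 replicate 1 let-7i-5p was at 0.39 and miR-22-3p at −0.42. limma gave 0 miRNAs at an adjusted p under 0.05 and 1 at an unadjusted p under 0.05, with a smallest adjusted p of 0.795.

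The rule for names took the 10 smallest p in each direction, none past the threshold. On the higher side these were also miR-183-5p (0.56), miR-16-5p (0.64), miR-221-3p (0.55), let-7a-5p (0.67), miR-1246 (0.48), miR-151a-5p (0.51), miR-494-3p (0.42) and miR-3651 (0.33), given as log2 differences. Of these, miR-183-5p and miR-3651 changed sign in 1 alternative each. On the lower side the rule also gave miR-331-3p (−0.46), miR-1234-5p_v19.0 (−0.53), miR-6088 (−0.47), miR-200b-3p (−0.44), miR-19b-3p (−0.61), miR-320e (−0.46) and miR-141-3p (−0.44). Of the names in both directions, miR-183-5p, miR-221-3p and miR-151a-5p passed the filter through shTRF2 alone, and miR-22-3p and miR-19b-3p through shControl alone. Without shControl replicate 2 the values of miR-16-5p, let-7a-5p and miR-151a-5p were 0.15, 0.09 and 0.07, and those of miR-1234-5p_v19.0, miR-6088, miR-320e and miR-141-3p were −0.18, −0.26, −0.21 and −0.23. Without shTRF2 replicate 2 those of miR-221-3p, miR-1246 and miR-494-3p were 0.29, 0.19 and 0.23, without shControl replicate 3 that of miR-183-5p was 0.28, and without shTRF2 replicate 1 that of miR-19b-3p was −0.09. Some values moved away from 0 instead, such as miR-183-5p to 0.87 without shControl replicate 1 and miR-494-3p to 0.70 without shControl replicate 2. The value of miR-19b-3p also rested on the first arrays of the repeated samples (−1.17), since with their repeat arrays instead it was −0.04. miR-320c and miR-320e, like the let-7 members, have near-identical relatives that one probe can bind, so their single values are uncertain. Of the 91 miRNAs, 36 had a higher and 55 a lower mean in shTRF2, with a median log2 difference of −0.12. Scaling on all probes shifted that median to 0.48, and 88 miRNAs were then higher, among them all 10 named here as higher and 7 of the 10 named as lower, the exceptions being miR-34a-5p, miR-22-3p and miR-320c. In 9 of 91 miRNAs (9.89%) the groups did not overlap, against 10% by chance, 1 of them higher and 8 lower in shTRF2. For 28 of 91 the 95% interval lay inside a 2-fold change both ways, and the median SE was 0.36.

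**Figure D2:**
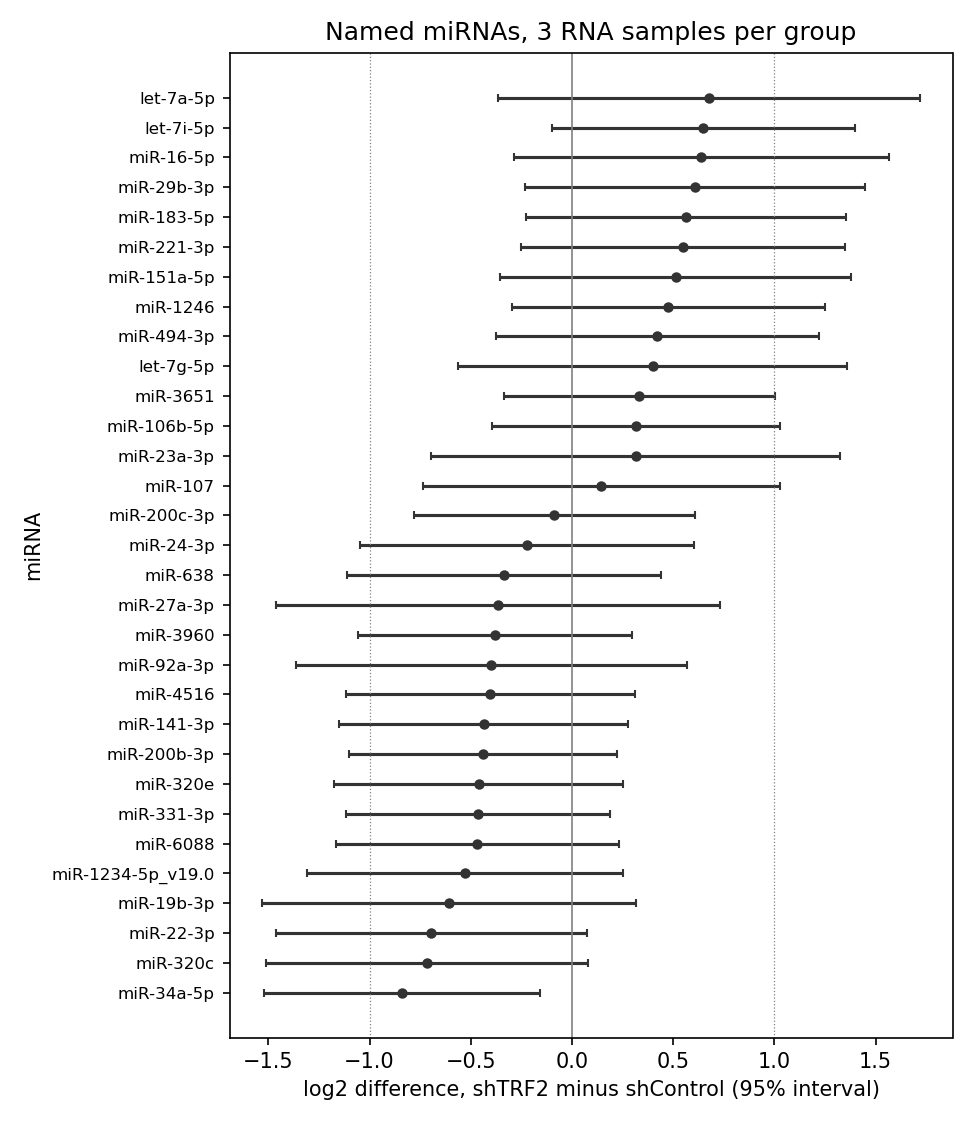
Log2 difference, shTRF2 minus shControl, of the 31 tested miRNAs named by rule (points) with 95% intervals from limma, 3 RNA samples per group. Dotted lines mark a 2-fold difference; the interval of miR-34a-5p alone leaves out 0, before adjustment.

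The third comparison asked whether whole miRNA families or functional lists moved together. The let-7 family, repressors of growth genes, had the smallest p of the lists by camera at its preset correlation, though not by fry: 5 of 8 tested members had higher means in shTRF2, with a median log2 difference of 0.41. By moderated t, let-7i-5p, let-7a-5p and let-7g-5p (0.40, and −0.13 without shControl replicate 2) came first. Its camera adjusted p was 0.106, and the adjusted p was 0.962 with an estimated correlation. Without shControl replicate 2 its direction turned, with a median of −0.27, and without shTRF2 replicate 1 the median was 0.26, the mean 0.10 and the camera adjusted p was 0.684. With shControl replicate 1 or 3, or shTRF2 replicate 2 or 3, left out instead, the camera adjusted p lay between 0.00104 and 0.0432, and the adjusted p between 0.756 and 0.995 with an estimated correlation. With the slide row as a term the mean difference was 0.57 and the camera adjusted p 0.000414, while the adjusted p was 0.551 with an estimated correlation. The GC-rich miRNAs, fixed as a sign of RNA quality, had lower means for 6 of 7 tested members, without passing the test (median −0.25, camera adjusted p = 0.391; median 0.08 without shControl replicate 2), among them miR-4516 (−0.40), miR-3960 (−0.38) and miR-638 (−0.34). The probes of miR-4516 ran from −0.40 to 0.10, and the mean of all its probes gave −0.15. miR-4516, miR-3960 and miR-638 were at −0.20, −0.24 and −0.01 without shControl replicate 2. shControl replicate 2 had the lowest let-7 mean (−0.62) and the highest GC-rich mean (−1.37) of the 8 arrays, on the log2 scaled signal.

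The epithelial miRNAs of the miR-200 family, which restrain mesenchymal transition, were lower for 3 of 3 tested members: miR-200b-3p, miR-141-3p and miR-200c-3p (−0.09), with a median of −0.44 and a camera adjusted p of 0.391. Without shControl replicate 2 the median was −0.23, and with the mean of all probes it was −0.12. miR-200c-3p turned to 0.11 without shTRF2 replicate 1. Under all-probe scaling that median was 0.19, below the 0.48 of all tested miRNAs. The p53-induced list split, with miR-34a-5p lower and miR-1246 and miR-107 (0.14) higher. Its median was 0.14, its mean −0.07 and its camera direction down (adjusted p = 0.924). Without shControl replicate 2 its median was −0.30 and its mean −0.23. Its direction turned up with the slide row as a term (mean 0.12) and without shControl replicate 3 (mean 0.04). The same held without shControl replicate 1, with quantile normalization and with the first arrays of the repeated samples alone. The growth-promoting miR-17-92 and paralogous clusters also split, with 3 of 6 members higher, among them miR-106b-5p (0.32), and 3 lower, among them miR-19b-3p and miR-92a-3p (−0.40). Their median was 0.06, their mean −0.04 and the camera direction up (adjusted p = 0.924), while without shControl replicate 2 the direction was down, the median −0.11, miR-106b-5p at 0.09 and miR-92a-3p at 0.03. In the miR-23/27/24 clusters, miR-27a-3p (−0.37), miR-24-3p (−0.22) and miR-23b-3p (−0.08) were lower and miR-23a-3p (0.31) was higher (median −0.15, camera adjusted p = 0.924). The sign of miR-24-3p turned in 7 of 25 alternatives, among them the total gene signal (0.30) and the mean of all probes (0.19). miR-27a-3p was at 0.00 without shTRF2 replicate 1, miR-23a-3p at −0.30 without shControl replicate 2, and miR-23b-3p at 0.04 without shControl replicate 1. These clusters passed without shControl replicate 2, lower in shTRF2 (median −0.46, camera adjusted p = 0.0142), and the adjusted p was 0.670 with an estimated correlation. The direction of the clusters was up without shControl replicate 1 (mean 0.14), without shControl replicate 3 (mean 0.13) and without shTRF2 replicate 1 (mean 0.03), and also with the total gene signal (median 0.30) and the mean of all probes (median 0.06). Up was also the direction with quantile normalization, the floor of 1 unit, the filter by Feature Extraction's detection, the repeat arrays alone, the slide row as a term and the authors' table. Without a filter, where miRNAs at the floor form the background, camera passed the epithelial, GC-rich, miR-23/27/24 and miR-17-92 lists as lower, with adjusted p from 2.11e-07 to 0.00326, and the smallest adjusted p of any list was 0.182 with an estimated correlation. With the filter, camera passed 0 of the 6 lists with at least 3 tested members, with 1 list at an unadjusted p under 0.05, and fry passed 0. Adjusted over the list alone, 0 members passed in any list, and 0 passed over all miRNAs tested.

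Smaller lists had too few tested members for a set test, and some members given here were named after their values were seen. miR-16-5p and miR-15b-5p (0.59) of the miR-15/16 family had higher means, but without shControl replicate 2 miR-15b-5p was at −0.19 and miR-16-5p at 0.15. miR-221-3p and miR-222-3p (0.41) of their cluster had higher means too, but miR-222-3p was at −0.11 without shControl replicate 3 and at 1.02 without shControl replicate 2. miR-15b-5p, miR-221-3p and miR-222-3p passed the filter through shTRF2 alone. In the miR-29 family miR-29b-3p was higher and miR-29a-3p (−0.08, and 0.06 without shControl replicate 3) lower. Of the miRNAs raised in colorectal tumours, miR-183-5p was higher and miR-21-5p (−0.18, and −0.05 without shTRF2 replicate 1) lower. miR-23a-3p was the 1 tested member of the list that targets telomere or telomerase genes, and miR-22-3p the 1 of the inflammation and senescence list. No member of these lists passed the test. Other cell types left little signal: the lists for blood cells, striated muscle, liver, stem cell clusters, the placental cluster and the imprinted cluster had 0 members well above background on any array. The vessel and smooth muscle list had 2 such members and 0 tested, the miR-30 family 1 and 0 tested, and the neuronal list had 1 tested member, miR-128-3p (0.18, and 0.04 without shControl replicate 2).

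**Figure D3:**
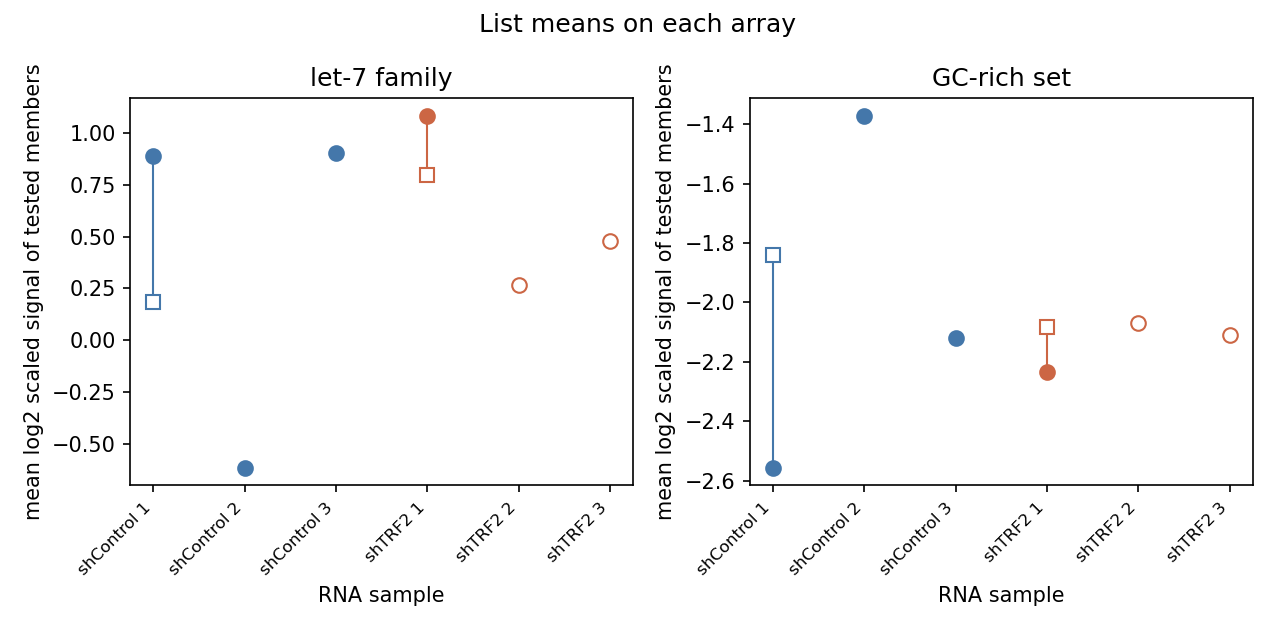
Mean log2 scaled signal of the tested members of the let-7 family and of the GC-rich set on each array, by RNA sample. Circles are first arrays, squares repeat arrays joined by a line, filled symbols slide row 1 and open symbols slide row 2; shControl replicate 2 has the lowest let-7 and the highest GC-rich mean, and the 2 arrays of shControl replicate 1 lie far apart.

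Repeat arrays gave the technical error, which includes any difference between the slide rows, since each repeat array lay in the other row. Across the 91 miRNAs, which are not independent replicates, the 2 arrays of shControl replicate 1 correlated at 0.902, with an SD of the log2 difference of 0.784, and those of shTRF2 replicate 1 at 0.947, with an SD of 0.570. Arrays of different RNA samples of one group correlated at 0.895 on average over 10 pairs, from 0.667 to 0.987. Those of different groups correlated no less, at 0.904 on average over 16 pairs, from 0.744 to 0.983. Pairs of arrays within slide row 2 averaged 0.978, those within row 1 averaged 0.826. With the slide row as a term, limma gave 0 miRNAs for the group and 0 for the row at an adjusted p under 0.05, and 1 and 11 at an unadjusted p under 0.05. Within row 1, 3 shControl arrays against 1 shTRF2 array, and within row 2, 1 against 3, limma gave 0 miRNAs in each at an adjusted p under 0.05, and 2 and 4 at an unadjusted p under 0.05. The lone array was assumed to vary like the others, in these fits and in their simulations, so neither row can tell its own spread from a group difference. In simulations of these fits, changes of 1 and of 3 on the log2 scale were recovered in 0.714% and 30.7% of cases in row 1, so its count of 0 says little, and in 62.9% and 96.4% in row 2. The let-7 mean was higher in shTRF2 by 0.69 in row 1 and 0.33 in row 2, and the GC-rich difference was −0.22 and −0.25. Both rows hold arrays of the replicate 1 RNA samples, so the rows are not independent, and row 1 holds shControl replicate 2.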

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

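Each named miRNA, list mean and array measure was examined over the 4 arrays of its group, of which 2 hold one RNA sample, for an array far from the others. Of 86 such sets, 6 had one, and chance marks about 1 in 20.

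On the first array of shTRF2 replicate 1 the mean of the miR-17-92 and paralogous clusters was −1.20, against −0.53 to −0.49 on the other shTRF2 arrays. On the same array miR-19b-3p of these clusters was at −3.14, against −0.60 to −0.32, and the repeat array of the same RNA was among the others. There miR-107 was at 0.0497, against −0.93 to −0.76, and miR-3960 at −2.24, against −1.75 to −1.66. In shControl, miR-151a-5p stood at −2.89 on the array of replicate 2, against −1.65 to −1.47, and miR-200c-3p at −0.13 on the first array of replicate 1, against 0.25 to 0.26. All are log2 scaled signals.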

How the results depend on the processing

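The pair of alternatives joining the authors' table with the 91 miRNAs, and the floor of 1 unit with Feature Extraction's detection, were chosen after seeing the data. limma gave 0 miRNAs past the threshold in all 25 alternatives, with 0 to 7 at an unadjusted p under 0.05 and smallest adjusted p of 0.0738 (without shControl replicate 2). The log2 difference of miR-193b-3p was below 0 in all 25, which the floor fixes wherever all shTRF2 samples sit at it, and ran from −1.73 (authors' table, where 1 shTRF2 sample is listed at 0) to −0.09 (all-probe scaling), with adjusted p from 0.124 up, the lowest in a setting chosen after seeing the data, and from 0.215 up in the planned ones. Lists past camera's threshold numbered 0 at first and 1, the let-7 family, with normexp, with the mean of all probes, with the RNA sample as a random block and with the slide row as a term (adjusted p from 0.000414 to 0.0394, and from 0.551 to 0.884 with an estimated correlation), and 4 without a filter, where miRNAs at the floor form the background. These 4, all lower by camera, were the epithelial and GC-rich lists (adjusted p = 2.11e-07 each), the miR-23/27/24 clusters (0.00238) and miR-17-92 and paralogous clusters (0.00326, though with a mean of 0.03), and the smallest adjusted p of any list was 0.182 with an estimated correlation. Leaving out single samples gave 0 to 1 lists, and the 1 without shControl replicate 2 was the miR-23/27/24 clusters, lower in shTRF2 (adjusted p = 0.0142, and 0.670 with an estimated correlation). The cause of these changes was not tested. With an estimated correlation 0 lists passed under any alternative. The mean correlation of repeat arrays stayed between 0.923 and 0.933. Of 31 named miRNAs, 12 kept their sign throughout, and 10 changed it under all-probe scaling alone, which raises all miRNAs together. The sign of miR-24-3p changed in 7 alternatives and that of miR-107 in 3. Signal over background limited the rest: 1848 miRNAs were not well above background on any array.

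The labels do not say whether the replicate numbers pair the samples. Same-numbered samples deviated together with r of 0.0848, 0.599 and 0.161, and differently numbered ones with r from −0.691 to 0.46. Not every sample correlated best with its own number, and so few values cannot decide on a pairing. With the number as a replicate block, limma gave 0 miRNAs, 2 at an unadjusted p under 0.05, a log2 difference of −0.32 for miR-193b-3p, and 1 list, the let-7 family (camera adjusted p = 0.0467, and 0.990 with an estimated correlation).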

Other observations

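The test of a shared row shift in the repeat arrays, and that of let-7 minus GC-rich without shControl replicate 2, were chosen after the results were seen. The patterns weighed below were themselves observed in these data. In the authors' log2 table, let-7i-5p had a mean higher by 0.86 in shTRF2 (SE 0.20), without passing the test (limma adjusted p = 0.238).

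The mean of miR-193b-3p was lower in shTRF2 after scaling, without passing the test, while its unscaled signals overlapped. The 62 miRNAs of like signal, within 1.5-fold, had a median log2 difference of −0.16 (bootstrap 95% interval −0.27 to 0.10). That lies above −0.45, which is 0.5 of the −0.89 of miR-193b-3p, so dim miRNAs as a set were not lowered that far. For miR-193b-3p itself the part of scaling can be read off, since each array had 1 divisor for all its miRNAs. The divisor ran from 122.1 to 253.2 units on shControl arrays and from 164.9 to 383.2 on shTRF2 arrays. On shTRF2 replicates 2 and 3 the unscaled signals of miR-193b-3p, 21.65 and 20.75 units, lay within the shControl range of 16.62 to 23.32. Hence their lower scaled values came from their divisors, 324.5 and 383.2. On both arrays of shTRF2 replicate 1 the unscaled signals, 10.08 and 10.11 units, were below those of every shControl array. Whether dividing by array brightness suits so dim a miRNA stays open. Under all-probe scaling, whose divisor falls among dim probes, the difference of miR-193b-3p was −0.09. The spread among dim miRNAs stays open as an explanation, since 9 of these 62 were lower still, which put miR-193b-3p at percentile 14.5. An effect of TRF2 silencing, the biological explanation in the design, stays open too.

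The repeat array of shControl replicate 1 correlated at 0.97 to 0.983 with arrays of other RNA samples in slide row 2, and at 0.902 with its own first array in row 1. The differences between first and repeat array of both repeated samples correlated at 0.102 (95% interval −0.11 to 0.30, across miRNAs, which are not independent). That argues against a shift of the same miRNAs by the row as the main part of both differences. A smaller row shift stays open, since noise of single arrays lowers this correlation. For the row, limma gave 11 miRNAs at an unadjusted p under 0.05 and 0 at an adjusted p under 0.05. Noise of dim probes did not show as a larger spread. The SD of these differences in dimmer miRNAs was 1.02 times that in brighter ones for shControl replicate 1 and 0.604 times for shTRF2 replicate 1. The floor limits how far dim miRNAs can move, so these ratios do not exclude such noise. What set the first array apart stays open, and no biological explanation was tested, as both arrays hold one RNA.

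The mean of the let-7 family minus that of the GC-rich set was 0.50 higher in shTRF2 on the log2 scale, and neither list passed its test. Array-to-array variation is a possible source: the same quantity moved by −1.42 between the 2 arrays of shControl replicate 1 and by −0.44 between those of shTRF2 replicate 1. A single sample is another, since shControl replicate 2 stood at 0.76 with the next lowest sample at 2.34, and without it the group difference was −0.20. An effect of TRF2 silencing stays open beside both, as untested.

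Of the 10 splits of the 6 RNA samples into 3 and 3, the real one gave 0 miRNAs at a limma adjusted p under 0.05, and the highest of the other splits gave 0. At an unadjusted p under 0.05, the real split gave 1 and the split of shControl 1, shControl 3 and shTRF2 1 against the rest gave 18, a split picked as the highest of the 10. For lists, the real split gave 0 and the highest other gave 2. No split can give fewer than a real count of 0, so these counts decide nothing, and with 10 splits no share under 0.05 can be reached.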
